A study of Mus musculus with 7 samples.

How the data were processed

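Libraries were made from total RNA of GFP-positive cells sorted from arches 3 to 6 of mouse embryos at embryonic day 10.5, with an RNA integrity number of at least 9.5 in every sample, per the labels' protocols. Those protocols name a strand-specific library kit, depletion of ribosomal RNA, random fragmentation and random priming. Controls carried Wnt1-Cre2 and unmodified Chd7, and mutants carried Wnt1-Cre2 and floxed Chd7 on both chromosomes, per the labels. The parental cross stated there, with floxed Chd7 on both chromosomes of the mothers, would give every embryo at least 1 floxed copy, so the Chd7 genotype of the controls was taken as labelled and any recombined copy in them is open. The labels number the wild-type libraries 1 to 4 and the deletion libraries 1, 3 and 4. They name no litter, date, sequencing batch or number of embryos, so p-values measure the spread between these libraries, which may be partly technical.

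The authors deposited 1 table of FPKM values, with 1 column for each of the 7 libraries and no pooled column. The submitters' processing notes name bcl2fastq 2.18.0.12, Trimmomatic 0.38, HISAT2, SAMtools, Partek and the mm10 build, with no role or order. The annotation, the filters, the use of strand in counting and whether fragments or reads were counted are not given in the sources used here. Nor do these sources say whether all 7 libraries were processed in the same way. FPKM divides the reads of a gene by its length and by the library total, so a library in which abundant transcripts take more reads has lower values for all other genes. The sum of FPKM ranged from 170809.1 in Chd7 deletion 1 to 209559.7 in wild type 4. Rn45s, a precursor of ribosomal RNA that depletion should remove, took 4.11% of the sum in wild type 4 and 8.68% in Chd7 deletion 1. Genes of a near-identical family, and genes that overlap a neighbour on the other strand, can share reads in ways the table does not show.

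The table held 19169 rows. In 25 rows a date stood in place of a gene symbol, as spreadsheet software writes it, and these rows were left out because a date can stand for more than 1 gene. They held between 0.153% and 0.166% of FPKM in each library. The remaining 19144 symbols were unique. Gene positions came from matching symbols to the GENCODE annotation of GRCm38, the build that mm10 names, which held 99.18% of the tested symbols. The authors' own gene models may differ in their ends.

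Depth was read from the values. Among genes whose highest value was below 0.2 FPKM, the ratio of values between libraries gave the relative depth, which was 1.29 for wild type 2, 1.12 for Chd7 deletion 1, 1.03 for Chd7 deletion 3, 0.996 for wild type 3, 0.912 for wild type 4 and 0.865 for Chd7 deletion 4, against wild type 1. Values were then searched for whole-number ratios, accepting a rounding error of up to 0.1 read. Whole reads were found for 81.3% of 17274 genes searched and for 76.98% of the genes tested, so they served only as an alternative and to show the depth behind low genes. In simulated tables of 1394 genes, reads were recovered for 98.78%, and for 2.94% of genes made of noise. Some read numbers are too high for their FPKM. In Chd7 deletion 4, Hba-a2 came out at 4021 reads at 3.03 FPKM, and the longer gene Hand2 at 455 reads at 7.52 FPKM. Intervals for counting error were not derived from these reads.

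Genes with a mean of at least 1 FPKM over the 7 libraries (11039) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance, 2-sided, and Benjamini-Hochberg adjustment over all genes tested at 0.05. The log2 fold change is the deletion mean minus the wild-type mean on that scale. The folds in the text are ratios of mean FPKM. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The steps were tested on simulated values for the Chd7 deletion comparison (11021 genes), in which 64% of genes changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 3-fold or 4-fold were recovered, and 5.24% of the 191 calls were false. The simulated noise was independent between genes and libraries and held no library sets. Changed genes were drawn only from those with a wild-type mean above 2 FPKM. These rates therefore need not hold for the real libraries or for lower genes.

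Before the data were examined, 33 gene lists were fixed from general knowledge, for the cell types, pathways and technical signs that arch neural crest might show. The lists hold 643 genes, 47 of them in more than 1 list. The 30 lists with at least 3 tested members were tested with camera at its preset correlation between genes of 0.01, with fry, and with camera at an estimated correlation, adjusted over the 30 lists. Camera compares a list with all other genes, so its direction can differ from the sign of the list median. The list of genes linked to CHD7 in other tissues came from general knowledge, not from these libraries. The named genes were fixed by a rule at the same stage. It takes Chd7, the 12 higher and 12 lower genes with the largest log2 fold change among called genes whose groups do not overlap, up to 4 called members of each list by smallest p, and for a list without any the member with the smallest p. Predicted-gene symbols were to be counted and not named, and none was called. The rule gave 58 genes, of which 37 passed the threshold. Foxc2 and Foxf1 are named as arch patterning genes beyond the 4, since other lists name them.

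Replicate numbers shared by both genotypes come from the sample titles. The deviations of same-numbered libraries from their genotype means correlated at 0.70 for replicate 1, 0.40 for replicate 3 and 0.77 for replicate 4 across genes, each above the highest correlation with another number, so the numbers were taken to pair the libraries. Genes are not independent replicates in these correlations. Within a library set (replicates 1 and 2, or 3 and 4) few numbers compete, so the match is weak evidence of pairing. Values with the replicate number as a block stand beside a result where they change its call or move its count by over 1.5 times. Wild type 2 has no partner, so under the block it adds nothing to the genotype difference, and few residual degrees of freedom remain. Camera with an estimated correlation rests on those degrees of freedom and has little power there. Its adjusted p ran from 0.538 to 0.834 over the 30 lists, so a call lost in that test says little against a list.

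Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, median-ratio, upper-quartile and quantile scaling, variance without a trend or with a robust fit, weights per library, the replicate block, the Y-linked genes as a covariate, an adjusted p of 0.1, a fold of at least 1.5, non-overlap of the groups, and each library left out in turn. The library set (replicates 1 and 2 against 3 and 4) as a covariate, replicates 3 and 4 alone, limma-voom on whole reads, and removal of a trend with gene length and GC content (loess, span 0.5), with and without the replicate block, were added after seeing the data. Leaving out 1 library also changes the share of each library set in its genotype. The shares differ in the main fit too, with wild type 1 and 2 but only Chd7 deletion 1 from replicates 1 and 2. They lie furthest apart without Chd7 deletion 1, the only deletion library numbered 1 or 2, and next without wild type 3 or wild type 4. They are equal without wild type 1, wild type 2, Chd7 deletion 3 or Chd7 deletion 4. Lists that differ between the sets can move with these shares.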

Results

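RNA was sequenced from cells positive for green fluorescent protein (GFP) that had been sorted from pharyngeal arches 3 to 6 of mouse embryos at stage E10.5. In these embryos Wnt1-Cre2, a recombinase expressed in the neural crest, switched on the GFP of the mTmG reporter, so that neural crest cells and their descendants carried the label. The libraries fell into 2 groups, with 4 from embryos labelled wild type for Chd7 and 3 from embryos in which the same recombinase removed floxed Chd7. CHD7 is a chromatin remodelling enzyme, and mutations of the human gene cause CHARGE syndrome, which includes malformations of the heart outflow tract. The comparison addressed which genes lie downstream of CHD7 in the cardiac neural crest. Expression was given as FPKM, read numbers scaled for gene length and library total, for 19144 gene symbols, of which 11039 had a mean of at least 1 FPKM and were tested. Sequencing depth, read from the steps between low values, ranged from 0.86 to 1.29 times that of wild type 1, and the genes whose values came out as whole reads held 6341996 reads in Chd7 deletion 4 and 9079760 in wild type 2. These totals include some read numbers that are too high for their FPKM.

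Chd7 itself was reduced in every Chd7 deletion library. Its level was 14.2 FPKM ± 0.337 (SD, n = 4) in the wild type and 7.71 FPKM ± 0.208 (SD, n = 3) after deletion, 54.3% of the wild type. The wild-type libraries lay between 13.9 and 14.6 FPKM and the deletion libraries between 7.5 and 7.91 FPKM. The log2 fold change was -0.80 with a standard error of 0.062 (limma, adjusted p = 0.00266), and an exact two-sided permutation test over the 35 splits of the 7 libraries gave p = 0.0286, the smallest value this design allows. Chd7 lies on chromosome 4 of mm10 from 8690406 to 8867659. The values cover the whole gene, and the labels do not name the floxed part, so transcript that lacks only the deleted part still counts towards the level after deletion.

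**Figure D1:**
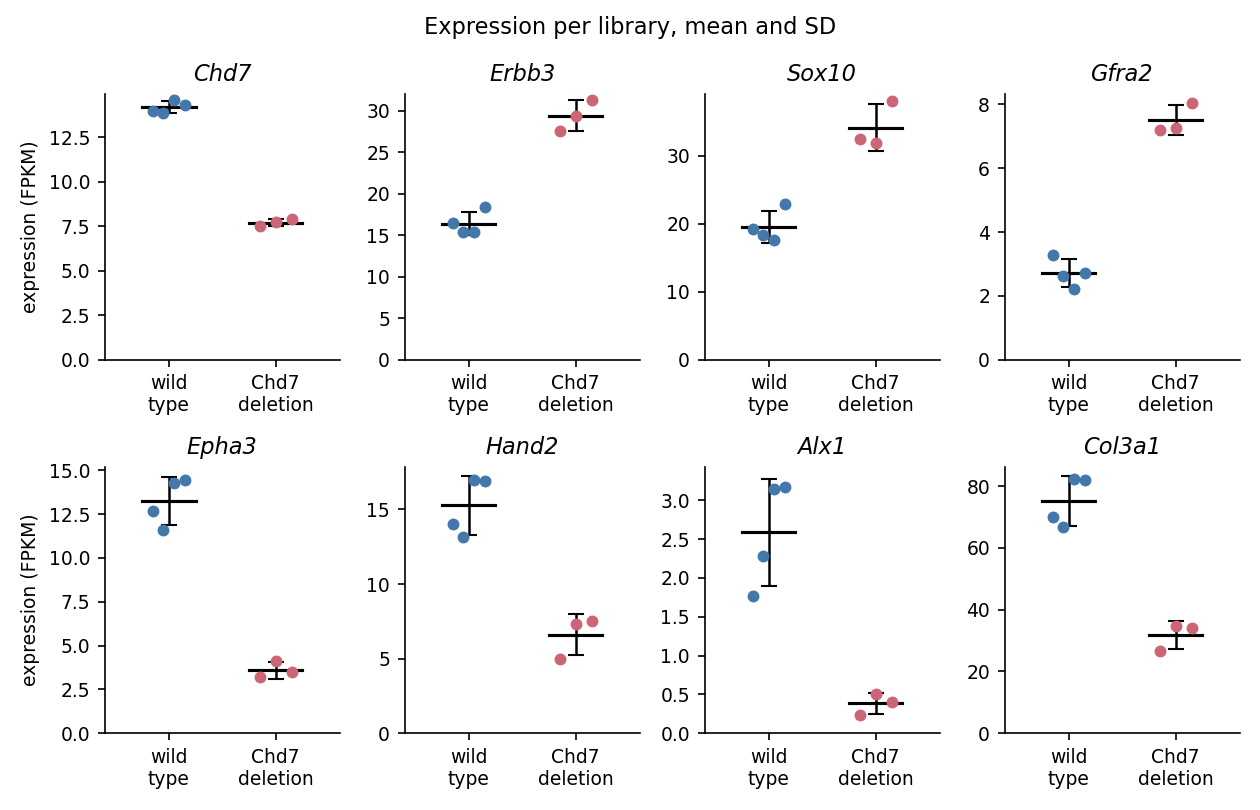
Expression in FPKM (vertical axes, from 0) of Chd7 and 7 changed genes in each wild-type library (blue, n = 4) and each Chd7 deletion library (red, n = 3). Points are libraries, and the black lines are the mean and SD. Chd7 fell from a mean of 14.2 to 7.71 FPKM, and no wild-type point overlaps a deletion point in any panel.

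After deletion of Chd7, 4 of 14 glial genes and 1 of 5 melanoblast genes rose, and 6 of 29 genes that pattern the arches fell. All 3 lists passed camera, but the arch list did not with an estimated correlation (adjusted p = 0.236), and none did with an estimated correlation under the replicate block (adjusted p = 0.538 for each). That last test has little power with so few libraries, and no list of the 30 came below an adjusted p of 0.538 in it. Sox10, a transcription factor of the glial and melanocyte lineages, was 1.75-fold higher (19.5 ± 2.38 FPKM, SD, n = 4, against 34.1 ± 3.46 FPKM, SD, n = 3), and the neuregulin receptor gene Erbb3 was 1.79-fold higher (16.4 ± 1.43 against 29.4 ± 1.83 FPKM). Epha3, which encodes a receptor for ephrins, was 3.7-fold lower (13.2 ± 1.37 against 3.58 ± 0.469 FPKM), and Hand2, a transcription factor of the arches and the heart, was 2.31-fold lower (15.3 ± 1.96 against 6.61 ± 1.4 FPKM). In all, 98 of 11039 genes passed an adjusted p of 0.05 in limma, 45 of them higher and 53 lower after deletion, and 815 had an unadjusted p below 0.05. The values of the groups did not overlap for any of the 98 genes. Among all genes tested the groups did not overlap for 9.17%, where chance gives 5.71%. Folds of at least 2 were reached by 7 of the higher genes and 23 of the lower ones.

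The libraries numbered 1 and 2 stood apart from those numbered 3 and 4 in both genotypes, on a first principal component that held 60.5% of the variance, while the second, with 16.5%, separated the genotypes. Numbers 1 and 2 cover wild type 1 and 2 but only Chd7 deletion 1, so the main fit mixes part of this difference with the genotype. With the replicate number as a block the count rose to 366 (115 higher, 251 lower), including all 98. Wild type 2, without a partner, adds nothing to the genotype difference in that fit. The median log2 fold change of all genes was -0.04 in the main fit and -0.07 under the block, on FPKM not rescaled between libraries. The share of lower genes and list medians near 0 are to be read against that offset. With replicates 3 and 4 alone the count was 139 (53 higher, 86 lower), of which 74 were among the 98. The count depended on single libraries, and was 4 without wild type 3 or without Chd7 deletion 4, 12 without Chd7 deletion 3, 35 without wild type 2, 40 without wild type 1 and 53 without wild type 4. The genes Epha3, Chd7, Six2 and Gfra2 were called whichever library was left out.

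**Figure D2:**
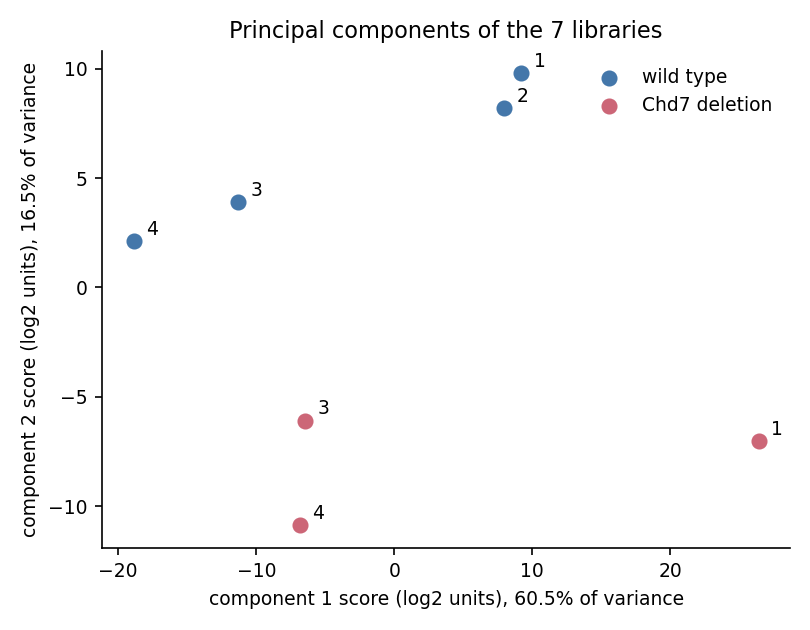
Scores of the 7 libraries on the first and second principal components of the log2(FPKM + 1) values (axes in log2 units), labelled by replicate number, with wild type in blue and Chd7 deletion in red. The first component held 60.5% of the variance and parts replicates 1 and 2 from 3 and 4, and the second held 16.5% and parts the genotypes.

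Of the 12 higher genes with the largest changes, Gfra2 had the largest log2 fold change on the log2(FPKM + 1) scale (1.2, against 0.84 for Rxrg), with a 2.76-fold increase in mean FPKM from 2.72 ± 0.437 to 7.51 ± 0.476 FPKM (SD; n = 4 and n = 3). Gfra2, on chromosome 14 from 70890120 to 70979838, encodes the receptor for the growth factor neurturin. Dct, an enzyme of melanin synthesis, rose 2.34-fold from 1.83 ± 0.165 to 4.28 ± 0.434 FPKM. Rxrg, a nuclear receptor gene, rose 2.86-fold from 0.739 ± 0.149 to 2.11 ± 0.174 FPKM, on 40 to 73 reads per wild-type library and 142 to 183 per deletion library. Erbb3 and Sox10, given above, were also in this group. The remaining 7 were Flrt1, Afap1l2, Stard13, Fhdc1, Cd200, Fgd5 and Gas7, with log2 fold changes from 0.66 for Gas7 to 0.84 for Flrt1. Their adjusted p in limma lay between 0.0111 and 0.0447.

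The 12 lower genes with the largest changes included several genes of transcription factors. Alx1 fell from 2.59 ± 0.688 to 0.383 ± 0.135 FPKM (SD; n = 4 and n = 3), a 6.77-fold difference that rests on 138 to 244 reads per wild-type library and 21 to 41 per deletion library. Hmx1 was 5.26-fold lower (3.03 ± 1.06 against 0.576 ± 0.122 FPKM), Tbx15 3.32-fold lower (3.48 ± 0.398 against 1.05 ± 0.364 FPKM), Foxp2 2.51-fold lower (8.14 ± 1.14 against 3.24 ± 0.68 FPKM) and Barx1 2.35-fold lower (8.79 ± 1.35 against 3.73 ± 0.921 FPKM). Agtr2, the gene of the type 2 angiotensin receptor, fell 8.91-fold from 2.51 ± 0.778 to 0.281 ± 0.185 FPKM, with 14 to 46 reads per deletion library. Epha3, on chromosome 16 from 63543534 to 63864175, had the largest log2 fold change, -1.64 with a standard error of 0.103 (limma, adjusted p = 0.00137). The other lower genes of this group were the collagen gene Col3a1, the matrix genes Sparcl1 and Efemp1, the guidance gene Sema3a and Hand2, with log2 fold changes from -1.22 for Col3a1 to -1.0 for Sema3a. These fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes such as Agtr2, Alx1 and Hmx1.

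**Figure D3:**
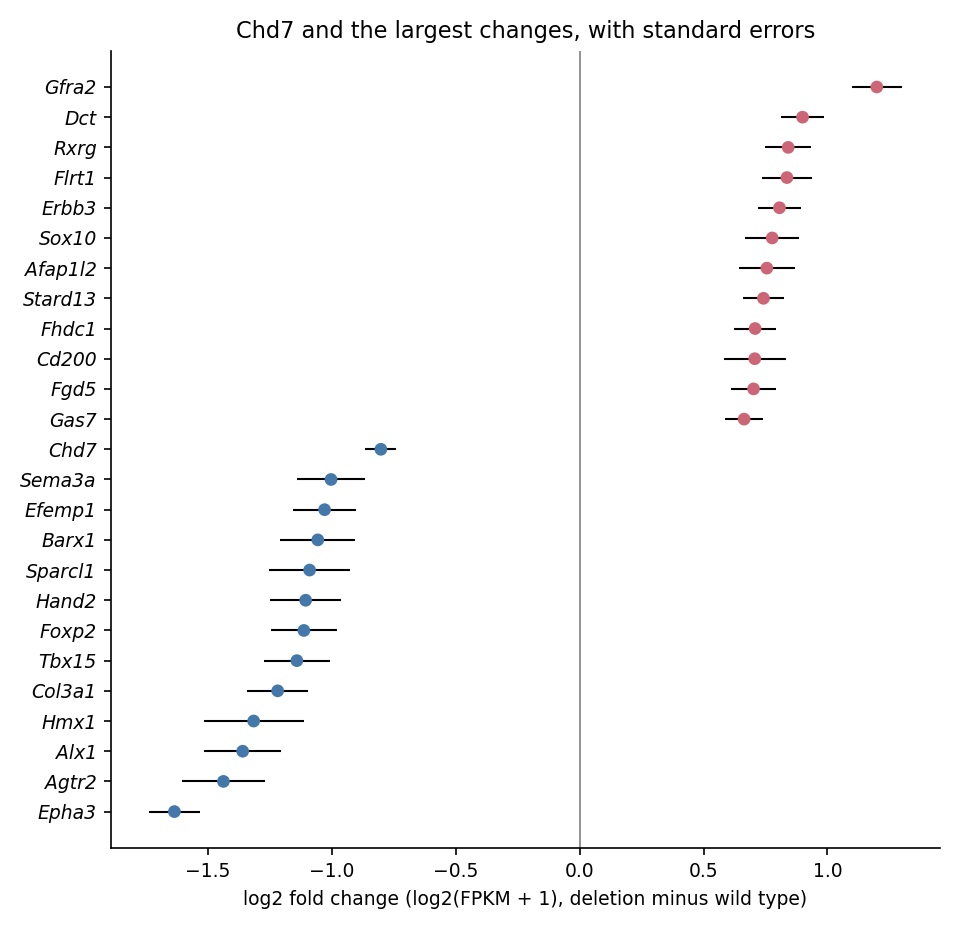
Log2 fold changes (horizontal axis, Chd7 deletion minus wild type, on log2(FPKM + 1) values) of Chd7 and the 12 higher (red) and 12 lower (blue) genes with the largest changes. Bars are standard errors. Epha3 lies lowest at -1.64 and Gfra2 highest at 1.2.

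Genes of Schwann cell precursors and glia were higher as a group after deletion of Chd7. Of 14 members tested, 4 rose (Sox10, Erbb3, Foxd3 and Gas7), none fell, and 13 had a log2 fold change above 0, with a median of 0.46. Adjusted over the list alone, 8 rose. Foxd3, a transcription factor of early neural crest and glial precursors, was 1.54-fold higher (12.9 ± 0.683 FPKM, SD, n = 4, against 19.8 ± 1.25 FPKM, SD, n = 3). The list passed the camera set test (adjusted p = 1.68e-19) and did so with an estimated correlation (adjusted p = 0.0268), but not with an estimated correlation under the replicate block (adjusted p = 0.538), the highest of its 26 alternatives, of which the lowest was 6.11e-20. Melanoblast genes moved the same way. Of 5 tested, 1 rose (Dct, with 2 under the replicate block), all 5 rose when adjusted over the list alone, and the median was 0.53 (camera adjusted p = 1.40e-11, or 0.0445 with an estimated correlation and 0.538 with it under the replicate block, in a range of 4.91e-14 to 0.538 over 25 alternatives). By library set, the melanoblast median was 0.59 in replicates 3 and 4 and 0.20 in replicates 1 and 2, and the glial median 0.53 and 0.29. The glial and melanoblast lists were the only ones past the threshold with an estimated correlation, and under the replicate block, where that test has little power, none was.

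Neural crest specifiers were divided. Of 23 tested, 3 rose (Sox10, Foxd3 and Sox8, of which Sox10 and Foxd3 also stand in the glial list) and none fell. Sox8 was 1.57-fold higher (10.3 ± 1.1 FPKM, SD, n = 4, against 16.1 ± 1.44 FPKM, SD, n = 3), with wild type 4 at 11.9 FPKM, apart from the other wild-type libraries (9.53 to 9.88 FPKM). Adjusted over the list alone, 5 rose and 4 fell, and under the replicate block 3 rose and 4 fell. The list median was 0.20 (camera adjusted p = 0.00168), and the call was lost with an estimated correlation (adjusted p = 0.552, in a range of 7.86e-05 to 0.561 over 26 alternatives).

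Genes that pattern the pharyngeal arches were lower as a group. Of 29 tested, 6 fell, none rose, and 28 had a log2 fold change below 0, with a median of -0.43. The genes Six2, Alx1, Hand2, Barx1, Foxc2 and Foxf1 were the 6, and 19 fell when adjusted over the list alone or under the replicate block. Six2 was 2.2-fold lower (9.37 ± 0.33 FPKM, SD, n = 4, against 4.26 ± 0.325 FPKM, SD, n = 3), Foxf1 was 1.85-fold lower (11.6 ± 1.47 against 6.25 ± 0.903 FPKM) and Foxc2 1.5-fold lower (6.43 ± 0.433 against 4.29 ± 0.421 FPKM). The list passed camera (adjusted p = 4.28e-20) but not with an estimated correlation (adjusted p = 0.236, in a range of 3.14e-24 to 0.538 over 26 alternatives). In fry, which tests whether the members moved one way on balance, its adjusted p was 0.0298. Hox genes of the arches had a median of -0.13, with none of 14 past the threshold (2 fell under the replicate block, and 3 when adjusted over the list alone). Their camera call (adjusted p = 0.00211) was lost with an estimated correlation (adjusted p = 0.552, in a range of 5.68e-07 to 0.561 over 26 alternatives). It was lost too without Chd7 deletion 4 (adjusted p = 0.147).

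Genes of the outflow tract and arch arteries were mostly on the lower side, with 2 of 44 past the threshold (Hand2 and Foxc2, both also arch patterning genes), 10 lower and 1 higher when adjusted over the list alone, and 10 lower and 3 higher under the replicate block. The median was -0.12 (camera adjusted p = 6.19e-04), and the call was lost with an estimated correlation (adjusted p = 0.552, in a range of 5.25e-06 to 0.561 over 26 alternatives). Without Chd7 deletion 3 the adjusted p was 0.0724. Among axon guidance ligands and receptors, 4 of 41 fell (Epha3, Sema3a, Robo1 and Efnb2) and none rose. Sema3a, a secreted repellent, was 2.44-fold lower (6.07 ± 1.23 FPKM, SD, n = 4, against 2.49 ± 0.288 FPKM, SD, n = 3), the receptor gene Robo1 1.44-fold lower (17.5 ± 0.913 against 12.1 ± 0.5 FPKM) and the ephrin gene Efnb2 1.42-fold lower (27.4 ± 0.791 against 19.4 ± 1.15 FPKM). Adjusted over the list alone, 10 fell and 2 rose, and under the replicate block 8 fell and 3 rose. The list median was -0.10 (camera adjusted p = 0.0223). The call was lost under the replicate block (adjusted p = 0.689) and with an estimated correlation (adjusted p = 0.718), in a range of 4.49e-07 to 0.775 over 26 alternatives. The axon guidance call was lost as well without wild type 1 (adjusted p = 0.244), wild type 2 (adjusted p = 0.0913), Chd7 deletion 3 (adjusted p = 0.238) or Chd7 deletion 4 (adjusted p = 0.556, with the median at 0.01). In each of these fits the library sets had equal shares in both genotypes, which they have not in the main fit. With the library set as a covariate the camera adjusted p was 0.775. By set, the median was -0.05 in replicates 3 and 4 and -0.02 in replicates 1 and 2.

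Hedgehog, BMP and FGF response genes had list medians below 0, and Notch pathway genes a median above 0. The Hedgehog list also holds co-receptor genes such as Gas1, and the BMP list receptor and ligand genes. The medians of these lists therefore do not give the direction of signalling. Of 11 Hedgehog response genes 2 fell, the co-receptor gene Gas1 (30.1 ± 2.58 FPKM, SD, n = 4, against 19.5 ± 0.26 FPKM, SD, n = 3) and the target gene Foxf1, with 7 lower and 1 higher when adjusted over the list alone and 4 lower under the replicate block. The median was -0.21 (camera adjusted p = 1.83e-05, or 0.133 with an estimated correlation, in a range of 5.26e-07 to 0.538 over 26 alternatives, and 0.00639 in fry). Of 19 BMP response genes 1 fell, the receptor gene Bmpr1b (2.88 ± 0.122 against 1.75 ± 0.133 FPKM), with 5 lower and 1 higher when adjusted over the list alone and 4 lower under the replicate block. The median was -0.22 (camera adjusted p = 1.31e-04, or 0.422 with an estimated correlation, in a range of 8.14e-06 to 0.561 over 26 alternatives). None of 13 FGF response genes passed the threshold (1 lower when adjusted over the list alone, 4 lower under the replicate block), with a median of -0.13 (camera adjusted p = 0.0341, or 0.803 with an estimated correlation, in a range of 8.64e-04 to 0.803 over 26 alternatives). The FGF call was lost without wild type 3 (adjusted p = 0.0537), wild type 4 (adjusted p = 0.12) or Chd7 deletion 3 (adjusted p = 0.339). Wnt response genes (median -0.02, none of 11, camera adjusted p = 0.927) did not pass either test. Retinoic acid genes had none of 11 past the threshold (2 lower when adjusted over the list alone or under the replicate block, camera adjusted p = 0.697), with a median of 0.03 and a mean of -0.02. Notch pathway genes had a median of 0.14 and none of 15 past the threshold (camera adjusted p = 0.312). Under the replicate block 2 of them rose and the list passed (adjusted p = 1.32e-04, in a range of 7.77e-05 to 0.990 over 26 alternatives). With an estimated correlation under the replicate block the Notch call was lost (adjusted p = 0.561). The Notch median turned below 0 with weights per library (-0.08), without wild type 4 (-0.05) and without Chd7 deletion 1 (-0.03). Chd7 deletion 1 is the only deletion library numbered 1 or 2, the set in which Notch genes were higher (median 0.35). The fit without it thus mixes the set difference with the genotype. To a lesser degree, the fit without wild type 4 does so too.

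**Figure D4:**
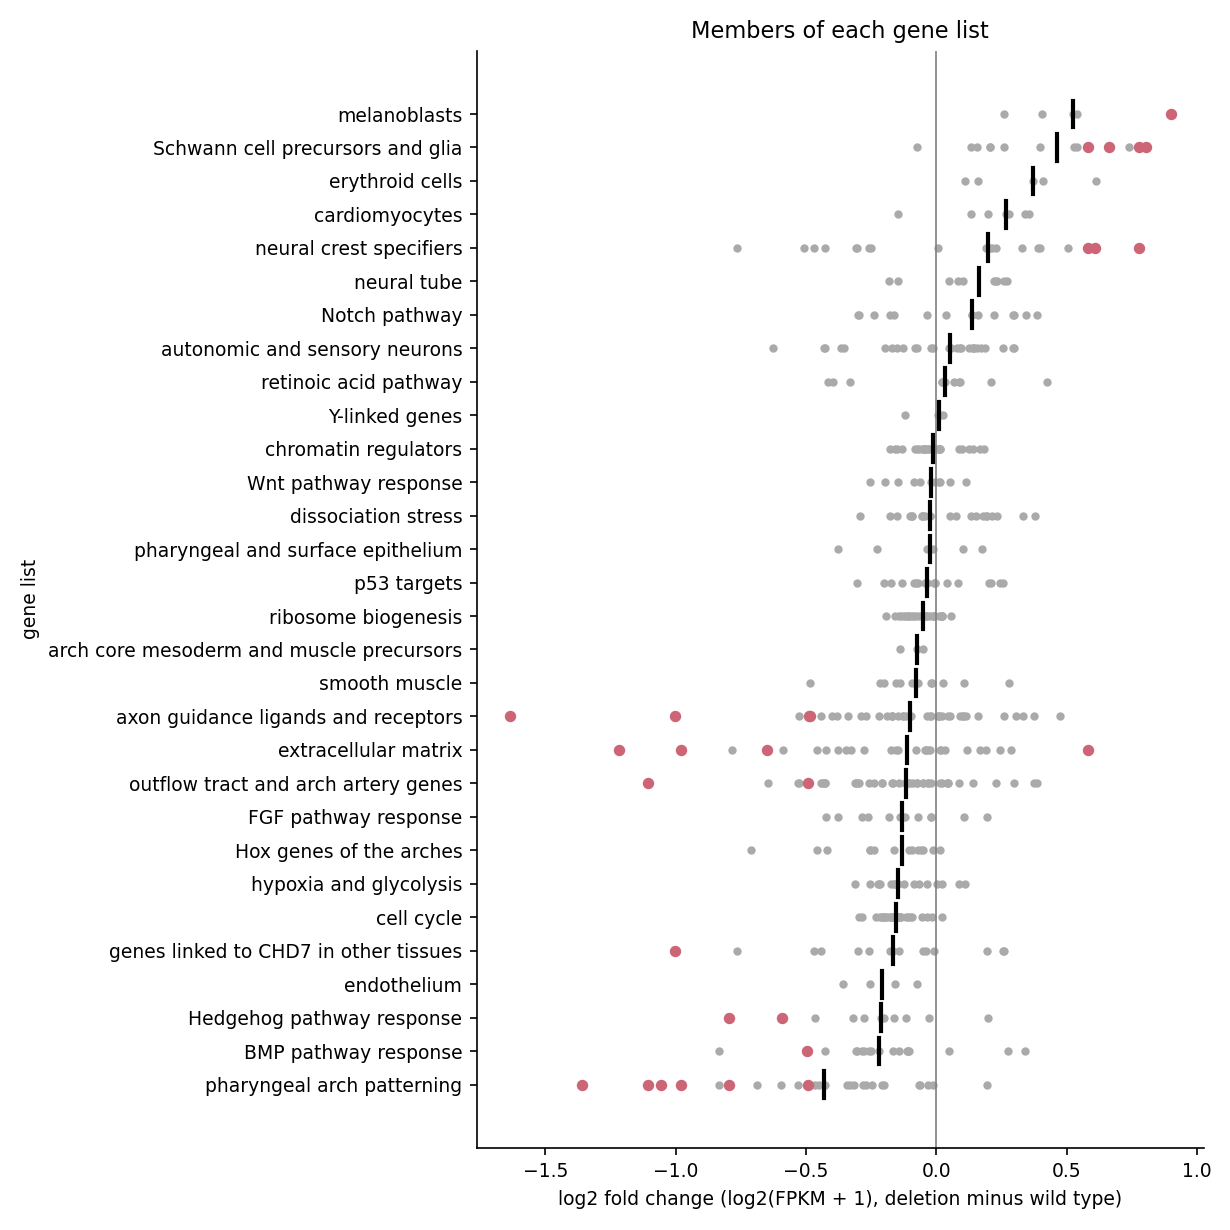
Log2 fold change (horizontal axis, Chd7 deletion minus wild type, on log2(FPKM + 1) values) of each tested member of the 30 gene lists (vertical axis). Red points are genes past an adjusted p of 0.05, grey points are the other members, and black bars are list medians. The medians run from -0.43 for arch patterning to 0.53 for melanoblasts.

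Extracellular matrix genes changed both ways. Of 28 tested, 3 fell (Col3a1, Col1a1 and Lum) and 1 rose, the laminin gene Lama4. Col3a1, a fibrillar collagen, was 2.36-fold lower (75.3 ± 8.06 FPKM, SD, n = 4, against 31.8 ± 4.51 FPKM, SD, n = 3), Col1a1 1.6-fold lower (26.4 ± 1.41 against 16.5 ± 1.05 FPKM) and the proteoglycan gene Lum 4.04-fold lower (1.92 ± 0.387 against 0.476 ± 0.124 FPKM). Lama4 was 1.55-fold higher (9.03 ± 0.752 against 14.0 ± 0.806 FPKM). Adjusted over the list alone, 8 fell and 3 rose, and under the replicate block 10 fell and 1 rose. The median was -0.11 (camera adjusted p = 0.0194). That call was lost under the replicate block (adjusted p = 0.0921) and with an estimated correlation (adjusted p = 0.803), in a range of 7.25e-04 to 0.803 over 26 alternatives. Without Chd7 deletion 3 the adjusted p was 0.166. Of 15 genes linked to CHD7 in other tissues 1 fell, Sema3a, with 5 lower when adjusted over the list alone and 4 under the replicate block. The median was -0.17 (camera adjusted p = 0.0105, or 0.12 under the replicate block and 0.422 with an estimated correlation, in a range of 4.46e-06 to 0.701 over 26 alternatives). This call was lost without wild type 1 (adjusted p = 0.0931), Chd7 deletion 3 (adjusted p = 0.0723) or Chd7 deletion 4 (adjusted p = 0.147).

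Cell cycle genes were slightly lower, with 29 of 30 below 0, a median of -0.15 and none past the threshold (1 lower under the replicate block). Their camera call (adjusted p = 0.00235) was lost with an estimated correlation (adjusted p = 0.803, in a range of 1.10e-07 to 0.803 over 26 alternatives). Without Chd7 deletion 1 the median was -0.04 (adjusted p = 0.138). That library is the only deletion library numbered 1 or 2, the set in which cell cycle genes were lower (median -0.30). The fit without it thus mixes the set difference with the genotype. No member passed the threshold, and no camera call was made, for smooth muscle (13 tested, median -0.08, adjusted p = 0.504), autonomic and sensory neurons (28 tested, median 0.05, mean -0.03, adjusted p = 0.312), p53 targets (20 tested, median -0.04, adjusted p = 0.527), ribosome biogenesis (28 tested, median -0.05, adjusted p = 0.697), chromatin regulators (31 tested, median -0.01, adjusted p = 0.282), or hypoxia and glycolysis (17 tested, median -0.15, adjusted p = 0.241). For p53 targets and chromatin regulators camera gave the upward direction although median and mean lay below 0. Adjusted over the list alone, 1 smooth muscle gene fell and 1 neuronal gene moved each way, and the other lists of this group had none. Under the replicate block 1 smooth muscle gene and 1 p53 target fell, 1 neuronal gene moved each way, and the neuronal list passed camera in the upward direction (adjusted p = 0.00145, in a range of 1.40e-04 to 0.990 over 26 alternatives). That call was lost with an estimated correlation under the replicate block (adjusted p = 0.561). The direction of the neuronal list turned, since it passed in the lower direction with weights per library (median -0.23, adjusted p = 0.0144) and without Chd7 deletion 1 (median -0.09, adjusted p = 0.0403). The fit without Chd7 deletion 1 mixes the set difference with the genotype here too, since neuronal genes were higher in libraries 1 and 2 (median 0.37).

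No tested marker of the other cell types that the sorted cells might include passed the threshold, but most listed markers were not tested. Those tested were 5 of 15 erythroid, 7 of 16 cardiomyocyte and 10 of 18 neural tube genes. For endothelium they were 4 of 16, for epithelium 6 of 22 and for arch mesoderm 3 of 14. The 5 erythroid genes had a median of 0.37 (camera adjusted p = 0.00582, or 0.552 with an estimated correlation, in a range of 9.77e-06 to 0.583 over 26 alternatives). Hba-a2, a globin gene, stood at 1.16 ± 0.253 FPKM (SD, n = 4) in the wild type and 2.43 ± 1.1 FPKM (SD, n = 3) after deletion, with 1.16 FPKM in Chd7 deletion 1 and 3.11 and 3.03 FPKM in Chd7 deletion 3 and 4. The direction of the erythroid list turned with the library set, with a median of 0.56 in replicates 3 and 4 and -0.20 in replicates 1 and 2. Its call was lost without wild type 4 (adjusted p = 0.0908) and without Chd7 deletion 3 (median 0.08, adjusted p = 0.0962). The 7 cardiomyocyte genes had a median of 0.27 (camera adjusted p = 0.0365, or 0.803 with an estimated correlation, in a range of 1.41e-04 to 0.854 over 25 alternatives), with Myh7 at 0.914 ± 0.584 and 1.38 ± 0.333 FPKM. The cardiomyocyte call was lost without wild type 1 (median 0.04, adjusted p = 0.510) or Chd7 deletion 4 (median 0.06, adjusted p = 0.352). The 10 neural tube genes had a median of 0.16 (camera adjusted p = 0.0578, and 3.47e-06 under the replicate block, the lowest in a range that reached 0.977 over 26 alternatives), with Sox2, which the glial list and the list of genes linked to CHD7 also hold, at 11.5 ± 2.14 and 14.0 ± 3.12 FPKM. The neural tube call under the replicate block was lost with an estimated correlation (adjusted p = 0.538). The neural tube median turned below 0 with weights per library (-0.17), without wild type 4 (-0.12) and without Chd7 deletion 1 (-0.15). The fits without Chd7 deletion 1 and without wild type 4 mix the set difference with the genotype more than the main fit does. Neural tube genes were higher in libraries 1 and 2 (median 0.48). By library set, the neural tube median was 0.26 in replicates 3 and 4 and 0.13 in replicates 1 and 2. Endothelial genes (4 tested, median -0.21, camera adjusted p = 0.161) passed under the replicate block (adjusted p = 0.0453, with 1 gene lower, in a range of 0.0313 to 0.988 over 25 alternatives), but not with an estimated correlation under it (adjusted p = 0.561). Epithelial genes (6 tested, median -0.02 with the camera direction upward, adjusted p = 0.927) and arch mesoderm (3 tested, median -0.07, adjusted p = 0.601) did not pass. None of the 17 genes of macrophages and other leukocytes reached the filter, and their highest mean in a genotype was 0.641 FPKM.

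No gene of the lists for handling and embryo sex passed the threshold. Dissociation stress genes had a median of -0.02 and a mean of 0.04 over 23 members, none past the threshold (camera adjusted p = 0.0978). Under the replicate block 1 of them rose and the list passed (adjusted p = 0.0369, in a range of 0.00159 to 0.942 over 26 alternatives), with list medians from -0.06 to 0.13. The stress call was lost with an estimated correlation under the block (adjusted p = 0.714). The 4 Y-linked genes had a median of 0.01, a mean of -0.02 and a camera adjusted p of 0.697, and Xist stood at 22.7 ± 6.55 FPKM (SD, n = 4) and 22.7 ± 8.11 FPKM (SD, n = 3). Every library expressed both Xist (14.0 to 31.5 FPKM) and the Y-linked gene Eif2s3y (2.97 to 6.44 FPKM). Each library may therefore hold cells of more than 1 embryo, of both sexes, which the labels do not state. The lists of X inactivation (1 member tested) and of mitochondrially encoded genes (none under the symbols used) were too small for a set test. Median-ratio, upper-quartile and quantile scaling each turned the medians near 0 of the Wnt response, p53 target, chromatin regulator, epithelial and dissociation stress lists above 0, and upper-quartile and quantile scaling did so for ribosome biogenesis.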

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

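All tests of explanations in this part were chosen after the results were seen. The bootstrap intervals given below resample genes as if independent and hold no spread between libraries. Genes of a list move together, with estimated correlations of 0.44 for arch patterning, 0.62 for Notch, 0.84 for cell cycle and 0.87 for neural tube. The intervals are therefore too narrow. A single value lay far from its group. Sox8 in wild type 4 stood at 11.9 FPKM, against 9.53 to 9.88 FPKM in the other wild-type libraries, and its gap to the nearest was 0.855 of the range, above the 95% limit of Dixon's test for 4 values. Among 62 items tested this way, chance gives about 3.1 such values. The value lies towards the level of the deletion libraries, so it narrows rather than makes the difference in Sox8.

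The count of 98 genes was set against all 35 splits of the 7 libraries into groups of 3 and 4. It was equalled or passed by 2 splits, the real one included, so a chance split of this kind cannot be excluded by that count alone. The other split placed the libraries numbered 1 and 2 (wild type 1, wild type 2 and Chd7 deletion 1) against the 4 numbered 3 and 4 and called 2613 genes, which points to a structure of the libraries that crosses the genotypes. No other split called more than 4 genes. Among the 8 splits that, like the real one, part all 3 numbered pairs, the highest other count was 0. Under the replicate block these form 4 distinct splits, since exchanging the groups in every pair gives the same fit, and the real one called 366 genes and the others 0. Neither 8 nor 4 splits can give a share under 0.05. For the gene lists, 7 of the 35 splits put at least as many lists past the preset camera threshold as the real 15, with 18 in the highest other and 10 in the split of the library sets, so chance cannot be excluded for that count. With an estimated correlation the real split gave 2 lists and every other split 0.

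Glial genes were higher and arch patterning genes lower after Chd7 deletion, with a gap of 0.89 between the list medians on the log2 scale (95% bootstrap interval over genes 0.55 to 1.11). A difference between the library sets as the whole cause is argued against, since the gap was 0.92 (0.68 to 1.16) with replicates 3 and 4 alone. With replicates 1 and 2 alone, where Chd7 deletion 1 is the only deletion library, the gap was 0.78. A dissection that took less of the anterior arches should raise the Hox genes that posterior cells carry. Their median was -0.13 (-0.26 to -0.06) and ran from -0.35 to -0.05 (without Chd7 deletion 4) over 26 alternatives, on the other side from that prediction. The explanation stays open, since their camera call was lost with an estimated correlation (adjusted p = 0.552). More neural tube cells in the deletion libraries cannot be told apart from the glial change by the list medians, since the glial median exceeded the neural tube median by 0.30 with an interval (-0.02 to 0.56) that reaches below 0, and the neural tube median itself ran from -0.17 to 0.41 over its 26 alternatives. It was below 0 only with weights per library, without wild type 4 and without Chd7 deletion 1. In each library set it lay above 0 (0.26 in replicates 3 and 4, 0.13 in replicates 1 and 2). A larger share of glial and melanocyte precursors among the sorted cells, or a change of expression within cells, may account for the pattern, and bulk values do not separate these.

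The libraries numbered 1 and 2 stood apart from those numbered 3 and 4. Over pairs of 1 wild-type and 1 deletion library, deviations from the genotype means correlated at a mean of 0.52 within a set. Between sets the mean was -0.52, a difference of 1.04. Same-genotype pairs of a set correlated at 0.50 (wild type 1 and 2), 0.40 (wild type 3 and 4) and 0.12 (Chd7 deletion 3 and 4). Deviations from a mean cancel within a genotype, so the negative value largely follows from the positive one and is not separate evidence. A different share of ribosomal RNA shifts all genes together, and as the whole cause it is argued against, since the set differences of the Notch and cell cycle lists lay 0.65 apart (95% bootstrap interval over genes 0.47 to 0.93; 0.62 in the wild type and 0.49 after Chd7 deletion), where the median of all genes differed by -0.14, while a trend with gene length and GC content as the whole cause is argued against by a difference of correlations of 0.90 (0.81 to 1.02) after its removal. More neural tube cells in the libraries numbered 1 and 2 may contribute, since all 10 neural tube genes were higher there, by a median of 0.48 (0.38 to 0.86) on the log2 scale, with Hes5 at 40.9 to 48.3 FPKM against 9.71 to 33.2 FPKM; Wnt1-Cre2 also marks dorsal neural tube, which dissection rather than the GFP gate removes, and the glial and Notch lists share Sox2 and Hes5 with this list. Whether it bears on genes with no known tie to the neural tube was not tested, such as Tmsb10 at 8.35 to 14.1 FPKM against 32.5 to 37.5 FPKM. Litter, exact stage, library batch and a different handling of reads or annotation in making the FPKM values of the sets, which could give steps such as Hist1h2ap at 74.1 to 78.8 FPKM against 0.0113 to 0.168 FPKM, stay open and were not tested, so the set difference may not be one of expression.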

How the results depend on the processing

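The library set as a covariate, replicates 3 and 4 alone, voom and the length and GC settings were chosen after seeing the data. Chd7 kept its direction and its side of the threshold in all 23 alternatives, with log2 fold changes from -0.87 to -0.75 and adjusted p up to 0.0308. The count of changed genes (98, of which 45 higher and 53 lower) stayed within 1.5 times under both other pseudocounts, variance without a trend, robust variance, voom (101) and an adjusted p of 0.1 (130). It was 366 (115 higher, 251 lower) under the replicate block, 720 (169 and 551) with the library set as a covariate, 213 (110 and 103) with weights per library, 206 (105 and 101) without the length and GC trend and 835 (428 and 407) when that was combined with the replicate block. Scaling by median ratio or upper quartile gave 156 each (81 and 86 higher, 75 and 70 lower), and quantile normalization gave 145 (74 higher, 71 lower). Lower genes were thus not in excess after scaling. These scalings shifted the median fold change of all genes by 0.04 to 0.05. The count was 62 (29 higher, 33 lower) without a filter and 32 (14 and 18) at 5 FPKM. A fold of at least 1.5 left 57 (19 higher). The Y-linked covariate gave 82 lower genes, and replicates 3 and 4 alone gave 86 lower. Groups did not overlap for 1012 genes (331 higher, 681 lower), a count that involves no adjustment. The cause of these differences was not tested, except that a fold limit removes genes by construction.

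With each library left out in turn, the count ran from 4 to 78, the higher genes from 1 to 42 and the lower from 3 to 36. Fewer libraries lower the power, but the cause of the spread between libraries was not tested. Of 36 called genes named beside Chd7, 33 lost their call without wild type 3 or without Chd7 deletion 4, 27 without Chd7 deletion 3, 15 without wild type 2, 10 without wild type 1, 6 without wild type 4 and 4 without Chd7 deletion 1, and none changed sign in any alternative. Under the replicate block all 36 stayed called and 7 other named genes passed (Hoxa5, Fgfr1, Synpo2, Dbh, Plk2, Plvap and Egr2). Apart from the calls given in the report, the block changed no list's call.

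The lists past the threshold (15) numbered 2 with an estimated correlation, 0 when that was combined with the replicate block, 4 in fry, and 9 (without Chd7 deletion 3) to 17 with a library left out. The estimated correlation combined with the block has little power, as given above. The list of autonomic and sensory neurons turned to the lower side and passed with weights per library (median -0.23, adjusted p = 0.0144) and without Chd7 deletion 1 (median -0.09, adjusted p = 0.0403). The fits without Chd7 deletion 1 and, to a lesser degree, without wild type 4 mix the library set with the genotype, as given above. With a library left out the median of the neuronal list ran from -0.10 (without wild type 4) to 0.25 (without Chd7 deletion 4), and the adjusted p over its 26 alternatives ran from 1.40e-04 to 0.990. Depth limits low genes most, as with Agtr2 at 14 to 46 reads per deletion library.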

Other observations

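Genes and lists in this part were chosen after their values were seen, and the choice follows their known roles. The genes given first are single ones among the 98 changed genes that no fixed list holds, and no enrichment was tested. Lgi4, a secreted factor needed for peripheral myelination, was 1.58-fold higher after Chd7 deletion (3.87 ± 0.30 FPKM, SD, n = 4, against 6.09 ± 0.41 FPKM, SD, n = 3; limma adjusted p = 0.0221). Sh3tc2, mutated in a demyelinating neuropathy, was 1.88-fold higher (0.96 ± 0.11 against 1.81 ± 0.082 FPKM, adjusted p = 0.0235), and the laminin receptor gene Itga6 was 1.56-fold higher (11 ± 0.48 against 17.2 ± 0.79 FPKM, adjusted p = 0.0111). Gpr17, known from oligodendrocyte precursors, was 1.51-fold higher (3.22 ± 0.28 against 4.86 ± 0.37 FPKM, adjusted p = 0.043).

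Other single genes chosen in this way were lower after Chd7 deletion. Vegfc, a growth factor for lymphatic vessels, was 2.29-fold lower (2.35 ± 0.39 against 1.02 ± 0.22 FPKM, limma adjusted p = 0.0315). Igf1 was 2.13-fold lower (4.96 ± 0.67 against 2.34 ± 0.57 FPKM, adjusted p = 0.032), Pdgfc 1.83-fold lower (11.2 ± 0.31 against 6.13 ± 1.1 FPKM, adjusted p = 0.0142) and the secreted Wnt antagonist gene Frzb 1.89-fold lower (12.6 ± 1.5 against 6.66 ± 1.0 FPKM, adjusted p = 0.0218). Shox2, a transcription factor of the sinoatrial node and of skeletal mesenchyme, was 2.13-fold lower (5.21 ± 0.44 against 2.45 ± 0.44 FPKM, adjusted p = 0.0111), and the nuclear receptor gene Nr2f1 was 1.39-fold lower (50.2 ± 0.77 against 36.1 ± 2.9 FPKM, adjusted p = 0.0366). For each of these genes the deletion and wild-type libraries did not overlap, as held for all 98 changed genes they were chosen from. Each call was lost when at least 1 library was left out.

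The library sets differed by steps at a few genes. In 4 of 11039 genes, every value of 1 set was over 5 times every value of the other. Hist1h2ap, a histone gene with near-identical copies, stood at 74.1 to 78.8 FPKM in the libraries numbered 1 and 2 and at 0.0113 to 0.168 FPKM in those numbered 3 and 4, while its relatives Hist1h2ao (105 to 163 FPKM) and Hist1h2ai (100.3 to 126 FPKM) showed no such step. The predicted gene Gm10052 stood at 0.157 to 0.239 FPKM in the libraries numbered 1 and 2 and at 3.32 to 11.9 FPKM in the others, and A230070E04Rik at 10.2 to 13.7 FPKM and 0.416 to 1.08 FPKM. The small nucleolar RNA gene Snora74a, the last of the 4, was listed at 0 to 0.161 FPKM and at 0.884 to 4.53 FPKM. Between the sets, all 30 cell cycle genes and all 28 ribosome biogenesis genes were lower in the libraries numbered 1 and 2, with medians of -0.30 and -0.25 on the log2 scale, where the median of all genes was -0.14, and all 15 Notch pathway genes were higher, with a median of 0.35. Afp, a fetal serum protein gene, stood at 0.49 FPKM in wild type 1 and at 6.27 to 15.7 FPKM in the other libraries.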
